A study of Nematostella vectensis with 17 samples.

How the data were processed

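Gene expression and Brachyury binding were measured in whole embryos of the sea anemone Nematostella vectensis at the gastrula stage. Per the labels, the series held 17 samples. Of these, 14 were RNA-seq libraries, with 6 from embryos injected with a translation-blocking morpholino, 4 with a splice-blocking morpholino and 4 with a control morpholino. The other 3 were ChIP-seq samples, 1 for each of 2 antibodies (AB1 and AB2) and 1 input. A morpholino is a synthetic antisense oligomer that blocks either the start of translation or the splicing of its target RNA. Per the labels, both brachyury morpholinos were injected at 500 µM in 3 to 5 pl, RNA was read as 50 bp single ends, and the replicates were biological. No concentration or volume was recorded for the control morpholino, so whether its dose matched was not known here. The protocol stated 6 replicates per group, and the 4 control and 4 splice libraries listed were used here.

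The RNA-seq table held raw counts per gene and library, as deposited by the authors, for 25729 gene models and 92 spike-in rows. The spike-in rows summed to 0 and were left out. The submitters' processing notes name cutadapt 1.8.1, STAR 2.5.3a, featureCounts, Subread 1.6.2, DESeq2 1.6.0 and BWA without giving their roles. Which annotation or strand setting was used for counting was not given in the sources used here, so overlapping and antisense genes and near-identical copies were not told apart. Rounded normalized values, deposited by the authors as a score for each library and group, were used only to identify the authors' comparison. Their deposited log2 fold change and fold (ratio) columns matched the ratio of the translation and control means, and the deposited p-value columns were read as that comparison. No column of per-sample values was left without a sample (0 columns).

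Each ChIP-seq antibody had 1 peak list without replicates, called by the authors for that antibody. Per the file headers, each peak had a position, a summit, a score, a ChIP signal, a control signal, a fold enrichment (ratio), a tag distribution score and an FDR. The FDR deposited by the authors reached 12.42 in the AB1 list, its scale was not stated, and it was not used. BWA and the genome build nemVec1 are named with the lists, while the peak caller was not given in the sources used here. Coordinates are on nemVec1 scaffolds, with starts taken as 0-based and given here as 1-based. Scores and folds are the authors' own and served only to describe, rank or filter peaks within a list. The input sample had no list and was not used beyond the control signal of the lists.

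Genes were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 on the counts of all 14 libraries. Genes were kept by filterByExpr (22109), libraries were scaled by TMM, and the fit had 3 group means and 11 residual degrees of freedom. All tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. The contrasts were translation minus control, splice minus control, the mean of both minus control, and splice minus translation. Standard errors are the absolute log2 fold change divided by the square root of F. CPM values were scaled by TMM, and log2 CPM used a prior count of 2. Each library counted as 1 replicate, since the labels call the replicates biological. All 27 pairs of libraries within groups differed by more than sampling noise, with a chi-square per degree of freedom of 8.25 to 54.4. That spread does not by itself show that the libraries are independent. On simulated counts, 2-fold changes were recovered at 75% for translation against control, 66% for splice against control, 82% for the combined contrast and 70% for splice against translation. Recovery of 4-fold changes was 100%, 98%, 99% and 98%, each out of 100 changed genes. The simulated libraries were drawn independently, and the changed genes had a control mean of at least 1 CPM. The recovery rates hold for that setting only.

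The rule for named genes, written before the data were examined, took genes called the same way with both morpholinos, with a mean of at least 5 CPM, by their combined log2 fold change. It also took the genes with the smallest adjusted p between the morpholinos. The files pair no gene names with the gene model identifiers, and 0 of the identifiers matched the RefSeq table of assembly jaNemVect1.1. Only 2 identifiers per direction are therefore given in each part, and the rule's requirement of a gene name was dropped. For the same reason brachyury itself was not analysed here as a gene, so the knockdown was not checked, and the fixed lists of pathway and cell type genes were not tested. Gene positions and the sequence of nemVec1 were not used here, so peaks were not assigned to genes or searched for T-box motifs, and binding was not set against expression.

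Peaks were compared with Python 3.11.15 and numpy 2.4.6. A peak was shared if it overlapped a peak of the other list by at least 1 bp, and 1000 circular shifts within scaffolds gave a one-sided permutation p. Scaffolds were taken to end at their last peak. Neighbouring shared AB1 summits at most 1000 bp apart were joined into chains and compared with 1000 random placements. DESeq2 1.42.0, limma 3.58.1 (voom), other scalings, filters, thresholds, leaving out each library, and stricter peak sets were the alternatives. Depth lay between 12289649 and 80132810 counts per library, and the spread between libraries exceeded counting error in every pair compared.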

Results

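Gastrula embryos injected with either of 2 non-overlapping brachyury morpholinos were compared with embryos injected with a control morpholino by RNA-seq. The dose of the control morpholino was not known here, so a difference in dose cannot be told apart from the effect of the brachyury morpholinos. Binding of Brachyury, a T-box transcription factor, was mapped by ChIP-seq with 2 antibodies raised in rabbits against the full-length protein, on chromatin fixed with 2% formaldehyde for 12 min. The 4 control libraries held 15236154 to 80132810 counts, the 6 translation libraries 12289649 to 32175949 and the 4 splice libraries 14873801 to 16096648. Control library 1 was the deepest, and the other 3 controls held at most 19126076 counts. Genes are given by the identifiers of the count table, which pairs them with no names.

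The first question was which transcripts changed in embryos injected with a brachyury morpholino. Averaged over both morpholinos, 1679 genes rose and 1712 fell against control, which was 15.3% of the 22109 genes tested. Of these, 803 and 477 were also called with each morpholino by itself, and 237 and 415 differed between the morpholinos. The genes were selected on the mean of both, and the median log2 fold change of those that rose was 0.72 with the translation morpholino and 0.69 with the splice morpholino, and that of those that fell was -0.69 and -0.65. Changes over 2-fold were found for 447 higher and 346 lower genes, and changes over 4-fold for 34 and 15. Among the called genes, 89 lay below 1 CPM in every control library and rose over 2-fold, while 54 lay below 1 CPM in every morpholino library and fell over 2-fold.

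Among the genes called the same way with both morpholinos at a mean of at least 5 CPM, NVE16580 had the highest combined change, with a log2 fold change of 3.53 ± 0.38 (SE) and an adjusted p of 2.5e-05 by edgeR. Its level was 2.89 ± 2.77 CPM in control embryos (SD, n = 4), 25.8 ± 2.81 with the translation morpholino (SD, n = 6) and 38.4 ± 7.39 with the splice morpholino (SD, n = 4). Control library 3 held 7.01 CPM, and without it the combined log2 fold change was 4.41. NVE23302 rose by 3.34 ± 0.78 (edgeR adjusted p = 0.0085), but its level varied between libraries, at 17.7 ± 22.9 CPM with the translation morpholino and 34.1 ± 22.7 with the splice morpholino against 2.54 ± 0.86 in controls. Without translation library 4 it was 3.52-fold higher with the translation morpholino, in place of 7.28-fold, and without control library 1 it was not called with that morpholino (edgeR adjusted p = 0.07). At a 1.5-fold minimum change NVE23302 missed the threshold (edgeR adjusted p = 0.053, with 9.9e-05 to 0.3 over all its alternatives). The lowest combined log2 fold change among these genes was that of NVE24009, -2.87 ± 0.25 (edgeR adjusted p = 5.3e-06). Its level went from 102 ± 24.1 CPM in controls to 8.92 ± 4.22 with the translation morpholino and 21.7 ± 7.57 with the splice morpholino. NVE7263 fell to near-equal levels with both, from 28.5 ± 4.96 CPM to 5.49 ± 0.776 and 5.23 ± 0.371, a combined log2 fold change of -2.41 ± 0.12 (edgeR adjusted p = 1.4e-08).

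Genes of all expression levels were among the calls. When the tested genes were cut into 3 equal classes by mean CPM, 12.7% of the low, 16.5% of the middle and 16.8% of the high class were called. In the low class more genes fell (566) than rose (369), and in the high class more rose (753) than fell (485). In 718 genes every morpholino library lay above every control and in 651 every one lay below, together 6.19% of the genes tested. Over all groupings of exchangeable libraries the mean would be 0.2%. Genes vary together and the libraries follow their title numbers, so that mean does not show how far a single grouping can lie from it. With library size as the only scaling, 37.3% of the combined calls were higher, against 49.5% with TMM. The combined count was 1538 without control library 1 and 1865 without control library 2. Libraries whose title number was at most 52970 (2 control, 3 translation, 3 splice) gave 3110 combined calls by edgeR, and the later ones (2, 3 and 1) gave 0, with 1948 genes at an unadjusted p under 0.05, 245 calls by DESeq2 and 0 by limma-voom.

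**Figure D1:**
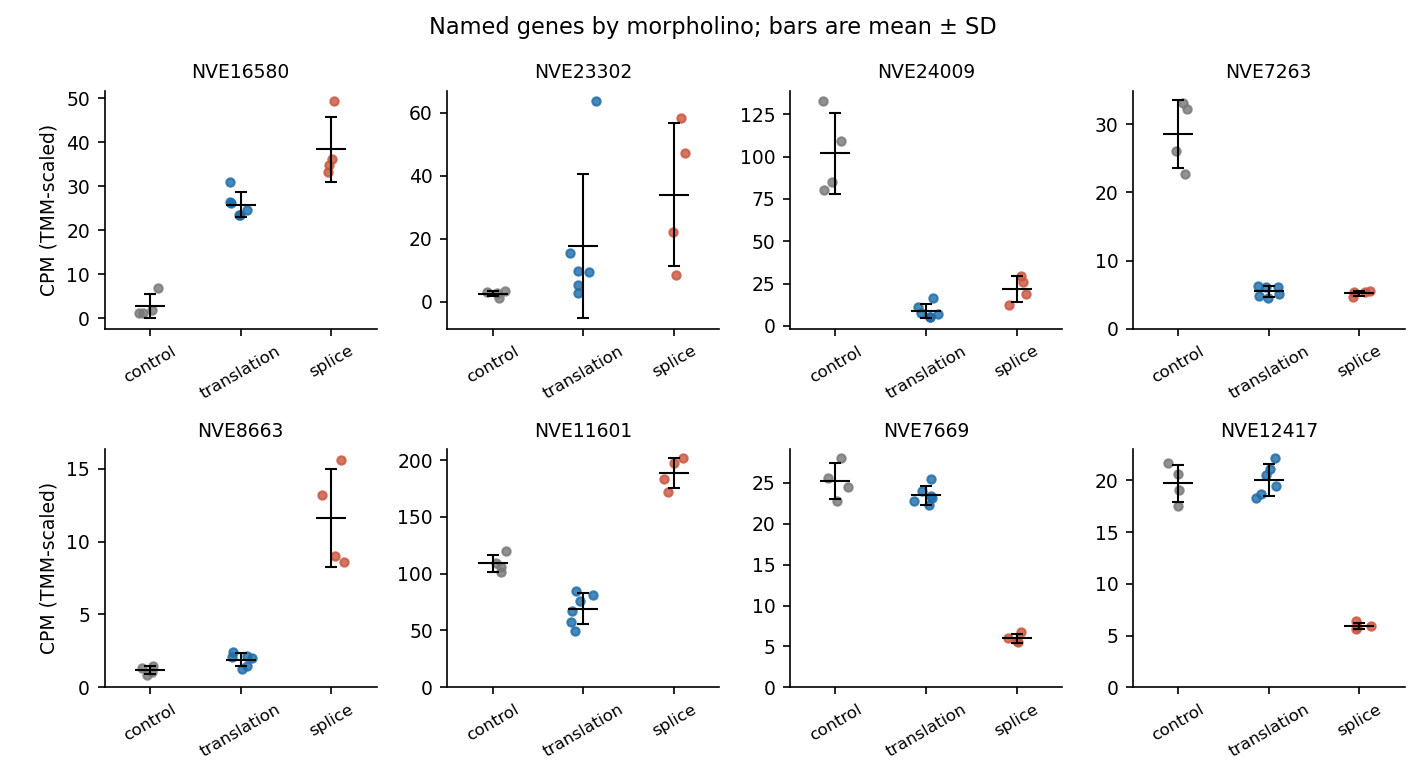
CPM of the 8 named genes in each library (y axis, TMM-scaled CPM) by injected morpholino (x axis), with 4 control, 6 translation and 4 splice libraries. Points are libraries and bars are the mean ± SD; NVE7263 lies at 22.7 to 33 CPM in controls and at 4.49 to 6.26 with the translation morpholino, while NVE7669 and NVE12417 have means of 5.99 and 5.92 CPM with the splice morpholino.

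The translation-blocking morpholino was then compared with control on its own. With it, 2202 genes rose and 2238 fell (20.1% of those tested), and 593 and 588 of them changed over 2-fold. The share of calls that were higher was 49.6%, and 40.5% with library size as the only scaling. NVE24009 was 11.3-fold lower (log2 fold change -3.5 ± 0.3, edgeR adjusted p = 2.9e-06) and NVE16580 was 9.46-fold higher, or 17.4-fold without control library 3. In the authors' deposited table for this comparison, 5243 genes had an adjusted p under 0.05, with 2749 higher and 2494 lower. Of the 4440 genes called here, 4409 were also called in the authors' deposited table, all with the same sign. The authors' deposited table gave NVE24009 a log2 fold change of -3.5 and NVE16580 one of 3.2. The count was 2454 without control library 1 and 2841 without control library 2. Libraries numbered up to 52970 gave 3005 calls and the later ones 19, and 95.6% of the former genes tested in both had the same sign in the later libraries.

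With the splice-blocking morpholino, 1272 genes rose and 1169 fell (11% of those tested), and 447 and 412 changed over 2-fold. NVE16580 was 14-fold higher (log2 fold change 3.81 ± 0.41, edgeR adjusted p = 3.3e-05), or 25.9-fold without control library 3, and NVE7263 5.45-fold lower (-2.45 ± 0.16, edgeR adjusted p = 4.9e-07). The share of calls that were higher was 52.1%, and 37.8% with library size as the only scaling. The count was 1272 without control library 1 and 1404 without control library 2. By edgeR, libraries numbered up to 52970 gave 2517 calls, or 1547 to 2736 with 1 of their 3 splice libraries kept. The later libraries gave 0, with 1683 genes at an unadjusted p under 0.05, 145 calls by DESeq2 and 0 by limma-voom; they hold 1 splice library, which was assumed to vary like the other groups. Of the former genes tested in both, 98.2% had the same sign in the later libraries. Their median absolute log2 fold change was 0.97 in the earlier libraries, on which they were selected. In the later libraries the median was 0.64 in the same direction. For the translation calls of the earlier libraries these medians were 0.98 and 0.62.

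A pair of non-overlapping morpholinos allows genes that change with both to be set apart. Called the same way with both were 803 higher and 476 lower genes, together 1279, and 23 genes were called in opposite directions. Of the latter, 16 were higher with the translation morpholino and lower with the splice morpholino, and 7 the reverse. Both comparisons used the same controls. In 40 simulations of unchanged groups against these controls no gene was called the same way with both (0 at most), but at most 1 gene was called in the simulated translation comparison, so that count does not measure what the shared controls add. Independent lists of these lengths would share 245 genes (127 higher and 118 lower). With the 4 controls divided so that each comparison had its own pair (6 ways), 327 to 483 genes were called the same way. The correlation of the log2 fold changes across genes, which are not independent replicates, was 0.6, against 0.53 in the simulations, and 68.3% of the genes had the same sign with both, against a simulated 68%. The simulated libraries were drawn independently, without the structure that follows the title numbers. The covariance of the observed changes was 0.149 against a simulated 0.0331, a difference of 0.116, and 0.108 to 0.143 with divided controls. Of the 1279 genes, 62.8% were higher, and 48.3% with library size as the only scaling. Without control library 1 the count was 635, and without control library 2 it was 718.

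**Figure D2:**
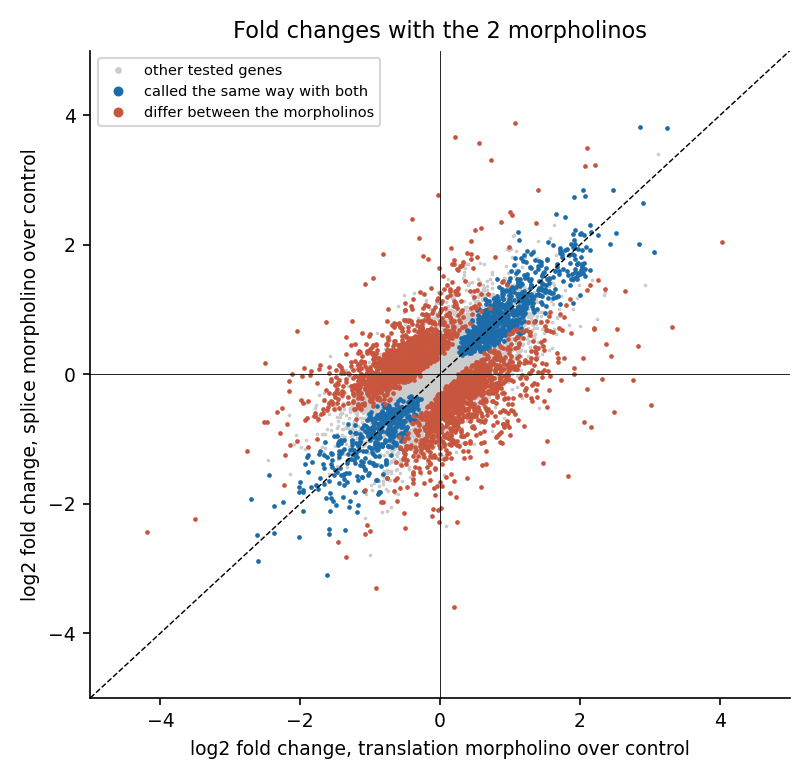
Log2 fold change over control with the translation morpholino (x axis) and the splice morpholino (y axis), 1 point per tested gene, with the dashed line marking equal change. Blue points are genes called the same way with both that do not differ between the morpholinos, and red points are the 2825 genes that differ; both axes share the control libraries, which alone gives a correlation of 0.53 in simulations.

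Finally, the 2 morpholinos were compared directly; the contrast sets no control mean against either, but its spread was estimated from all 14 libraries. Levels were higher with the splice morpholino for 1435 genes and lower for 1390 (12.8% of those tested), and 317 and 287 differed over 2-fold. NVE8663 stood at 11.6 ± 3.38 CPM with the splice morpholino (SD, n = 4), 1.9 ± 0.447 with the translation morpholino and 1.17 ± 0.262 in controls, a log2 difference of 2.59 ± 0.22 (edgeR adjusted p = 7.2e-06). NVE11601 moved in opposite directions, from 109 ± 7.76 CPM in controls to 69.3 ± 13.8 with the translation morpholino and 189 ± 13.4 with the splice morpholino (log2 difference 1.45 ± 0.13, edgeR adjusted p = 1.2e-05). NVE7669 was at 25.3 ± 2.18 CPM in controls and 23.5 ± 1.15 with the translation morpholino but at 5.99 ± 0.541 with the splice morpholino (log2 difference -1.97 ± 0.11, edgeR adjusted p = 5.9e-08). NVE12417 had the same pattern, with 19.7 ± 1.79, 20 ± 1.5 and 5.92 ± 0.325 CPM (log2 difference -1.76 ± 0.11, edgeR adjusted p = 3.2e-07). Of the 3138 genes called with the translation and not with the splice morpholino, 1119 differed between the morpholinos, and of the 1139 called with the splice and not with the translation morpholino, 574 did. Among the 1279 genes called the same way with both, 104 differed in size. The count was 1862 (887 higher, 975 lower) when the control libraries were left out of the fit, 1650 without splice library 1 and 1572 without splice library 4, and 43.1% of the calls were higher with library size as the only scaling, against 50.8%. By edgeR, libraries numbered up to 52970 gave 1015 such genes and the later ones, with 1 splice library, gave 0, with 3304 at an unadjusted p under 0.05, 464 by DESeq2 and 0 by limma-voom. With 1 splice library kept, the libraries up to 52970 gave 85 to 1732, so group size can account for part of the later 0.

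Brachyury binding sites were compared between the antibodies. The AB1 list held 14257 peaks and the AB2 list 16005. Shared peaks made up 10607 of the AB1 list (74.4%) and 11243 of the AB2 list (70.2%). Shifted placements shared 493 AB1 peaks on average and 659 at most (one-sided permutation p = 0.001, the smallest that 1000 shifts can give). The median distance between paired summits was 14 bp, and 92.8% lay within 50 bp. Sharing fell with the score, from 98.2% of the highest-scoring 10% to 42.3% of the lowest-scoring 10% of the AB1 list, and from 96.8% to 34.3% in the AB2 list. Shared AB1 peaks had a median fold enrichment of 4.48 and the others 2.89. There were no replicate lists, so these values carry no replicate error, and the shifts test position only, not agreement through the 1 input sample or shared chromatin bias. Both antibodies were raised against the same protein, and whether both also bind other proteins was not tested.

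The highest AB1 score among shared peaks was 71.11, on nemVec1 scaffold 286 at 137540 to 137783, with a fold enrichment of 85.29. The same site had the highest AB2 score, 95.23, with a fold of 156.3 and a summit 8 bp away. The next peaks lay on scaffold 4 at 1073865 to 1074108 (score 49.47), scaffold 62 at 666290 to 666533 (49.18), scaffold 10 at 2070081 to 2070324 (47.62) and scaffold 159 at 129088 to 129331 (42.23). Their AB2 partners ranked 2, 6, 11 and 3 in that list. Which genes lie at these sites was not analysed here.

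**Figure D3:**
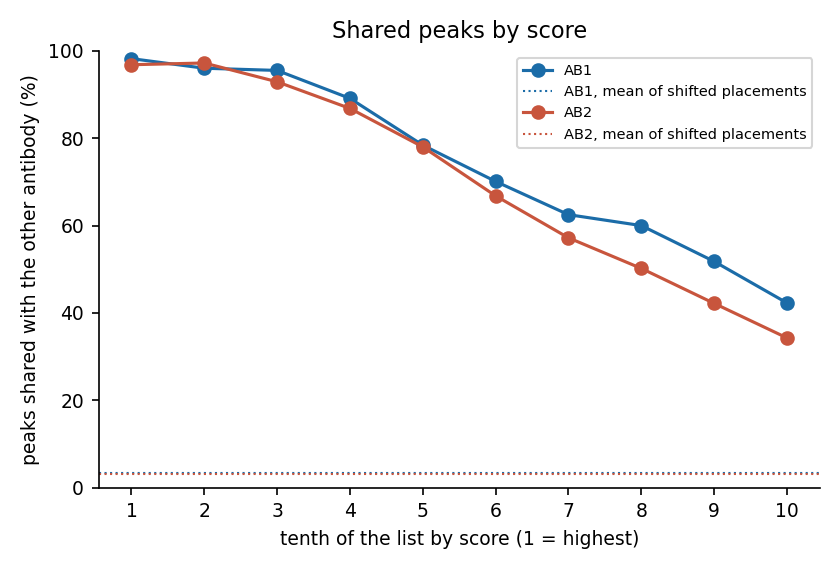
Percent of peaks shared with the other antibody (y axis) in 10 equal classes of each list by the authors' score (x axis, 1 the highest). Dotted lines mark the mean of shifted placements, 3.46% for AB1 and 3.18% for AB2, and every class of both lists lies above them.

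Shared peaks also lay close together. Of the 10607 shared AB1 summits, 2620 were followed by another within 1000 bp, against 511 on average and 584 at most in random placements (one-sided permutation p = 0.001, the smallest that 1000 placements can give). Joined in this way they formed 7987 regions, of which 6267 held 1 peak, 1194 held 2 and 526 held 3 or more. The region with the most peaks was on scaffold 126 at 310118 to 315291, with 14 shared peaks and a highest AB1 score of 9.66. The regions that followed lay on scaffold 84 at 594227 to 598741 (10 peaks) and scaffold 92 at 58552 to 62791 (9 peaks). The median peak width equalled the greatest width in both lists. The number of peaks in a region therefore need not be the number of separate binding sites.

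**Figure D4:**
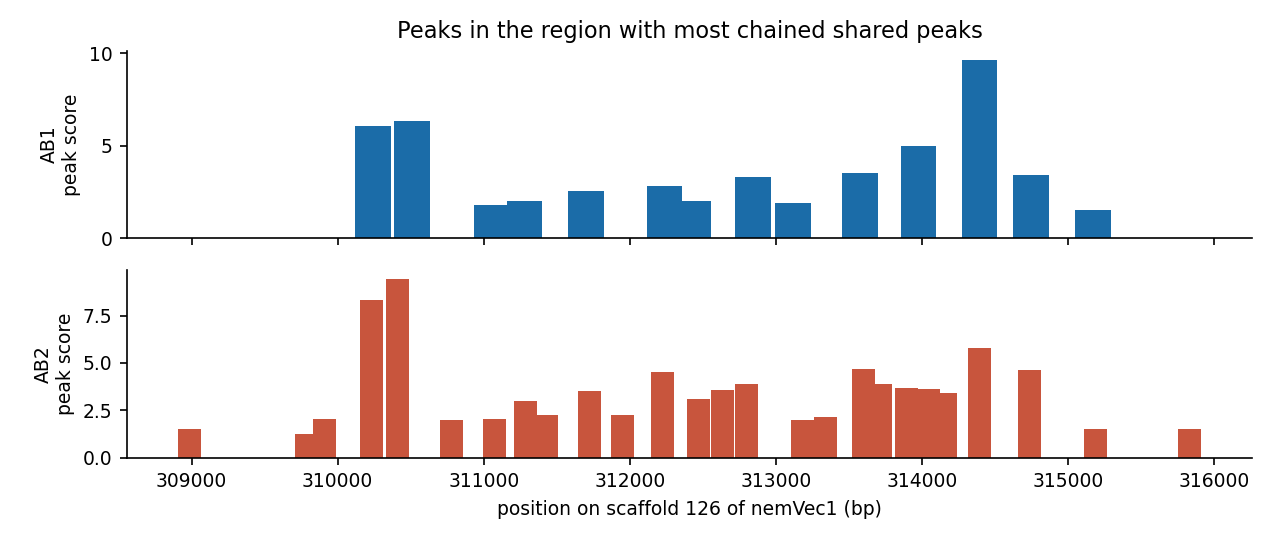
Peaks of AB1 (upper) and AB2 (lower) along scaffold 126 of nemVec1 (x axis, bp) with the authors' peak score as bar height (y axis) and the peak's start and end as bar width. The 14 shared AB1 peaks span 310118 to 315291, and the highest, scored 9.66, lies at 314272 to 314515.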

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

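Apart from leaving out libraries, the tests of explanations in this part were chosen after the results they bear on had been seen. The difference between the morpholinos was itself tested: 2825 genes differed, and among the named genes the log2 difference (splice minus translation) was 2.59 for NVE8663, 1.45 for NVE11601, 1.26 for NVE24009, -1.97 for NVE7669 and -1.76 for NVE12417. With every library thinned to the shallowest depth 2608 genes differed, and with the library number as a covariate 3358 did. The lowest count with 1 library left out was 1572, above the 859 of the highest other split drawn with every library. No splits were drawn with a library left out, so the 1572 has no matching set of splits. If the splice morpholino acted like the translation morpholino but more weakly, nearly every differing gene would change less with it. A smaller absolute change from control with the splice morpholino, whatever its direction, was found for 57.5% (95% jackknife interval over libraries 42.6 to 72.4, and 50.4 to 60.7 with 1 library left out). Effects of either morpholino on other transcripts, or different degrees of knockdown in different cells, may underlie the difference and were not tested.

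A few libraries stood apart from the others of their group, in 4 of the 39 sets of values examined. Chance flags about 1 set in 20, or 1.95 of the 39, so the number of flags does not by itself show aberrant libraries. Control library 1 stood apart in log10 total count (gap over range 0.863), and so did translation library 6 (0.639). Splice library 4 stood apart for NVE7263, with a gap over range of 0.841, but the shift was small, at 4.68 CPM where the highest splice library held 5.5. Translation library 4 stood apart on the third within-group component, at 0.68. That component was fitted to these same libraries, so the chance rate of 1 in 20 need not hold for it.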

How the results depend on the processing

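The library number covariate, the replicate block, the 2 parts of the numbering, the thinned depths and the control pairs were chosen after seeing the data. Under the other tools, scalings and low-count filters, all 5 gene counts stayed within 1.5 times their value. Counts are given in the order translation, splice, combined, splice against translation, and same way with both. A 1.5-fold minimum change left 490, 306, 320, 156 and 126 genes, and an adjusted p under 0.01 left 1915, 990, 1501, 982 and 501. Under 0.1, splice rose to 3786, splice against translation to 4478 and same way to 2050. Fitting only the groups compared gave 1862 genes for splice against translation, and cannot give the combined contrast. The library number covariate gave 1942 same-way genes. Leaving out 1 library gave 2454 to 4597, 1272 to 2862, 1538 to 3582, 1572 to 2921 and 635 to 1411. Libraries up to 52970 gave 1015 for splice against translation. The later ones gave 19, 0, 0, 0 and 0 by edgeR, beside 678, 145, 245 and 464 by DESeq2 for the first 4 and 0 by limma-voom. The low-numbered part reduced to the group sizes of the later one gave 3639 to 4203 combined calls, and the common dispersion of the later control and translation libraries was 2.41 times that of the earlier ones. With 2 controls the combined count went from 432 (controls 3 and 4) to 2977 (controls 1 and 2). Thinning control library 1 to the shallowest control gave 3184. The planned covariate of within-group variation lowers the residual spread by construction. No named gene reversed sign. Each of the 8 missed the threshold in the later libraries alone, which are fewer and vary more, at log2 fold changes of 3.05 (NVE16580), 3.8 (NVE23302), -2.26 (NVE24009), -2.31 (NVE7263), 2.2 (NVE8663), 1.48 (NVE11601), -2 (NVE7669) and -1.84 (NVE12417). Shared AB1 peaks numbered 5594 in the upper 50% of both lists by score and 734 in the top 1000, since fewer peaks were compared. The sample table gives no replicate number. A replicate block of 6 runs of title numbers, each starting at a translation library, gave 4815, 3245, 3909, 4029 and 1618 genes. Its 3909 combined calls held 2784 of the 3391 of the main fit. Of the 10 pairs within a block 7 correlated above 0.1, and 8 of 14 libraries correlated best within their block. Pairing required all 10 above 0.1, a bar that does not test for shared batches, and no chance value was computed for the 8 of 14. The other fits and the splits therefore ignore this sign of shared batches. Gene lists, peak location, bound genes and motifs, with their alternatives, were not run.

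Only 1 split, the real one, was as large for each count, with 100 of 210 drawn for translation and for splice against translation, all 35 for splice and 100 of 210210 for the rest. The real value and the highest other split were 4440 and 1238 for translation, 2441 and 1 for splice, and 3391 and 2215 combined. For splice against translation they were 2825 and 859, and for same way with both 1279 and 844. The splits ignore the structure along the title numbers and so cannot exclude chance. Without control library 1 or 2 the combined count (1538, 1865) and the same-way count (635, 718) lay below the highest other split of all 14 libraries. No splits were drawn without these controls.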

Other observations

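The tests in this part were all chosen after the patterns had been seen. High-scoring peaks of 1 antibody tended to score high with the other. Of the 3472 shared AB1 peaks in the top 25% of that list, 2838 (81.7%) had a partner in the top 25% of the AB2 list, against 908 of the 7135 other shared peaks (12.7%). The series had 1 input sample, and agreement of scores through a shared input or shared chromatin bias was not tested. Fold enrichment over 10 was listed for 1399 AB1 peaks and 2728 AB2 peaks.

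The closeness of shared peaks was set against 3 technical explanations. Random spacing gave at most 584 summits with a neighbour within 1000 bp, where 2620 were found. Of these neighbours 1539 lay at most 500 bp apart and 1081 farther. For the latter, 200 random placements gave 248 on average and 292 at most, so the excess was not confined to 500 bp. In both lists the median peak width equalled the greatest width, so no listed peak could span a longer enriched stretch. In the region with the most peaks, on scaffold 126, some neighbouring AB1 peaks overlapped each other. Whether longer enriched stretches were split into several peaks stays open, since the lists hold no signal between peaks. Collapsed repeats would raise the control signal, which in chains of 3 or more was 1.14 times that of single peaks (95% bootstrap interval 1.12 to 1.17). The bootstrap drew peaks and not regions, and peaks of the same chain are not independent, so the interval may be too narrow. The 5315 peaks at or below the median control signal had 656 near neighbours (4.69 times the random mean, 168 at most). The 5292 peaks above it had more, at 1022 (7.19 times, 167 at most). Closeness was thus not confined to peaks with a high control signal. A cut at the median does not separate collapsed from single-copy sequence, so repeats stay open for both sets. Groups of separate binding sites, or broad accessible stretches, may also account for the closeness, and neither was tested.

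Libraries of different groups with near title numbers deviated alike from their group means. Across genes, the 18 cross-group pairs with numbers at most 2 apart had a mean correlation of 0.16 and the other 46 pairs -0.06, a difference of 0.22 (one-sided permutation within groups, p = 0.0025), and 13 of the 18 were above 0. The main within-group component followed the number with Pearson r = 0.83 (permutation p = 0.0019, adjusted 0.011 over 6 relations) and Spearman rho = 0.84 (permutation p = 0.0019, adjusted 0.011) over 14 libraries, and r was 0.83 without the 2 farthest libraries. For depth, r with this component was -0.09 (95% interval -0.63 to 0.51, permutation p = 0.84, adjusted 0.84) and rho = -0.2 (permutation p = 0.57, adjusted 0.86). With the library number as a covariate, 719 of the 22109 genes tested had a called number term. The main fits leave this structure out. Embryo batches processed in the order of the numbers may account for the structure, which the labels do not state.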
